A study of Corynebacterium glutamicum R with 4 samples.

How the data were processed

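Chromatin immunoprecipitation followed by hybridisation to tiling arrays (ChIP-chip) was used to map where SigC, a sigma factor carrying a FLAG tag, sat on the chromosome of Corynebacterium glutamicum R, a soil bacterium of the actinobacteria. Sigma factors are the subunits of RNA polymerase that recognise promoters. Per the labels' protocols, cells were grown at 33 °C, crosslinked with 1% formaldehyde, and their DNA was sheared to a mean size of 600 to 1000 bp. Immunoprecipitated DNA (IP) carried Cy5 and unprecipitated reference DNA (input) carried Cy3 after linker ligation and PCR. There were 4 arrays, 2 per growth phase, from 2 experiments. No array of an untagged strain was analysed here, so each value is IP over input and not IP over a mock IP.

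Per the file headers, the arrays were read with Agilent Feature Extraction 10.5.1.1. The processed signals are intensities that the scanner software had already subtracted for background and normalized for dye, with a linear factor and a lowess curve, per the file headers. Median spot and background intensities and background-subtracted intensities without dye normalization were also deposited. The deposited LogRatio is log10 of Cy5 over Cy3. The authors' value table is in log2. It equalled the LogRatio of each array turned to log2, with a largest difference of 5e-10, so its scale and direction are known. It was not centred on 0 by a further step, and the medians of its columns over all spots were 0.00 for exponential 1, 0 for exponential 2, 0.02 for stationary 1 and 0.01 for stationary 2. A genome build for the probes is not given in the sources used here.

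Each array held 43803 spots measuring 40204 probes. Of these, 18462 probes belong to a forward-strand series and 18449 to a reverse-strand series, 3278 to a series with at least 2 spots per probe, called the gene series here, and 15 to a series with 10 spots per probe. The files give probe names but no positions, sequences or gene names for them. None of the names (0 of 40204) matched the gene table used as a reference, which is of another strain of the species. The gene lists, upstream regions, promoter motif and base-pair regions fixed before the data were examined were therefore not computed, and the rule for named genes (the genes that the files name for the 15 strongest probes of each phase) named no gene.

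Groups were taken from the sample titles, with which the growth characteristic agreed. The source field gives the other phase for stationary 1 and exponential 2. Taken literally it would place both arrays of each experiment in 1 phase, and it was used only as an alternative. Both arrays of experiment 1 lay on slide 1 and were read in scan 1, and those of experiment 2 on slide 2 and in scan 2, so experiment, slide and scan are 1 batch factor here and each batch holds both phases. The labels state that the experiments were independent. Same-numbered arrays deviated together from their phase means (Pearson r = 0.45 across 31315 probes). At the 7 regions they deviated in opposite directions, with exponential 1 below and stationary 1 above its phase mean at all 7. Across 24 summit probes of these regions the deviations also varied inversely (r = -0.53). The experiment number was treated as pairing the arrays because slide and scan are shared.

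The main value was log2 of processed Cy5 over processed Cy3. Control spots and spots marked as non-uniform were left out, spots of 1 probe were averaged, and each array was centred on its median. limma 3.58.1 in R 4.3.3 (lmFit, eBayes, two-sided) was fitted to all 4 arrays with phase as the only factor, over the 38098 probes with values on at least 3 arrays and in both phases. A probe was called enriched at a Benjamini-Hochberg adjusted p under 0.05 and a mean log2 ratio of at least 1. The phase comparison used the same adjusted p with no minimum size.

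Because positions were missing, runs of probe numbers took the place of regions, a rule set after the data were seen. A run was at least 3 consecutive numbers of 1 strand at which the mean over 3 numbers was at least 1.5-fold in the mean of the 4 arrays, and runs within 2 numbers were merged. That numbers follow the chromosome was tested on the values. Neighbouring forward numbers correlated with r = 0.45 and numbers 20 apart with r = 0.04. The reverse series ran the opposite way: forward and reverse probes correlated with r = 0.31 where their numbers added up to 18457, and with r = 0.03 at equal numbers. A region was a forward run and a reverse run whose summit numbers added up to within 10 of that sum. Its value per array was the mean of the 3 probes at each summit, 6 in all, fewer where spots were non-uniform. For the block of dim probes described in the report, the value was the mean of its 10 dim probes.

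A high probe on its own can pass the running mean, so the run rule was applied to 100 shuffles of the probe order. The forward strand then gave a median of 12 runs and at most 16, more than the 8 observed, and a count of runs alone therefore carries no weight. Mirrored pairs separated the data from the shuffles, with 8 observed, a median of 0 and at most 2. Without the running mean there were 7 forward runs, 7 reverse runs and 5 mirrored pairs, against 0 of each in every shuffle. The 8 pairs include the block of dim probes, and the sum was found on these same values. Shuffling also removes the correlation between neighbouring numbers. The comparison therefore shows that raised probes cluster at mirrored numbers, not that these places are bound.

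The tests were run on simulated arrays with the noise of each real array. For stationary minus exponential, 100 of 100 probes changed by log2 1 and 100 of 100 changed by log2 2 were called, with 13 false calls among 38098 probes. For enrichment in the exponential phase, 100 of 100 probes were recovered at log2 1.5 and 100 of 100 at log2 3, with 0 false calls. All 20 planted runs were found. The simulated noise was independent between arrays and probes, which the real noise was not, and the simulated background held no single high probes. Over all probes of an array, the real log2 ratios had an SD of 0.16 (exponential 1) to 0.22 (stationary 1). At the regions the SE of the phase difference was 0.85. The recovery of planted changes therefore does not show that changes of log2 1 or log2 2 would be called at the regions.

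Alternatives were another background correction (normexp, offset 50, on median signals because mean signals were not used here), loess within arrays, centring on the mode, scaling arrays to 1 spread, the authors' value table, filters on dim probes, other size thresholds, each array left out, the experiment number as a block, and grouping by the source field. The normexp setting also left out dye normalization, so it does not isolate the background correction. Others were added after the data were seen: non-uniform spots kept, probes with values on all 4 arrays, probes with input under 10% of the array median left out, signals without dye normalization, a crossed block, other run rules, and region 3 left out when regions were set against each other.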

Results

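SigC binding was measured in 4 two-colour arrays, with 2 cultures taken in the late exponential phase (optical density of up to 2.5) and 2 at the onset of the stationary phase (up to 7). The arrays are named exponential 1 and 2 and stationary 1 and 2 after phase and experiment. Median background-subtracted input signals lay between 30991 and 36630 intensity units and were 607 to 794 times the local background, and 0 spots were saturated. Non-uniform spots were more frequent in experiment 1 (7056 on exponential 1 and 4618 on stationary 1) than in experiment 2 (760 and 649). The number of arrays limits the precision.

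The first question was where SigC sat in each phase. The ratio of SigC-FLAG ChIP DNA over input was raised at 7 places on the chromosome, each seen on both strands, at about 4.72, 40.7, 54.3, 54.5, 57.8, 69.3 and 80.4% of the forward-strand numbering. They are called regions 1 to 7 in that order. Region 1 was the highest of them, with a log2 ratio of 2.45 ± 1.27 (SD, n = 2) in the exponential phase and 1.92 ± 0.94 (SD, n = 2) in the stationary phase, which correspond to 5.48-fold and 3.78-fold ratios of IP over input. Set against flanking probes, input was lowered more than IP was raised. Flanking probes are other probes, and differences in signal strength between probes were not removed, so this does not divide the ratio between the channels. Relative to flanking probes (6 to 15 numbers away, signals without dye normalization), IP at region 1 was 152, 164, 188 and 133% and input 59.0, 17.9, 35.1 and 54.6% on exponential 1, exponential 2, stationary 1 and stationary 2. Over the 7 regions the median IP of an array was 126 to 157% of the flanks and the median input 27.1 to 62.0%. Of the 28 values (7 regions on 4 arrays), input lay below the flanks in 28 and IP above them in 26, the exceptions being region 4 on exponential 1 (74.4%) and stationary 2 (81.4%), and in 28 the log2 fall in input exceeded the log2 rise in IP. Region 6 followed with 2.09 ± 1.17 and 1.60 ± 0.67. Tested as regions, all 7 passed in the exponential phase (limma adjusted p of at most 0.0117) and 4 in the stationary phase, where regions 3, 4 and 7 did not (limma adjusted p = 0.150, 0.0774 and 0.0825). The regions had been picked for their mean over all 4 arrays, so these p-values are not independent evidence of enrichment. The lowest stationary value was that of region 3, with 0.91 ± 0.59 against 1.87 ± 0.90 in the exponential phase. The forward runs of the 7 regions were 4 to 7 probe numbers long. Genes could not be named, because the files pair the probes with no positions or genes.

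**Figure D1:**
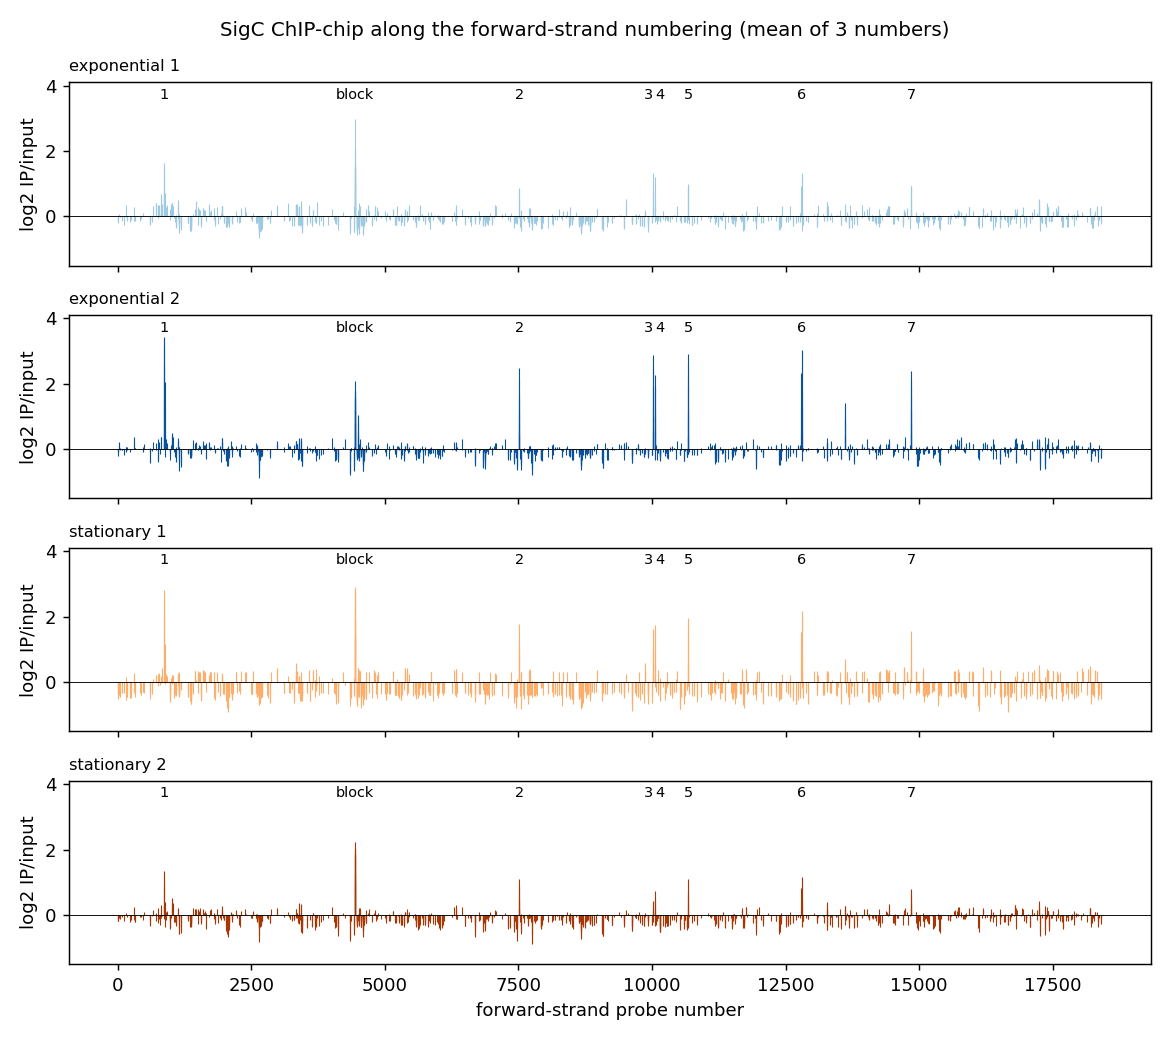
Log2 ratio of IP over input (y axis, mean of 3 probe numbers) along the forward-strand probe numbers (x axis) on each of the 4 arrays, drawn only for numbers at which any array lay at least 0.3 from 0. Numerals mark regions 1 to 7 and "block" the probes with dim input, and the summit of each of regions 1 to 7 stays within 1 probe number over the 4 arrays.

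At the level of single probes, 41 were enriched in the exponential phase and 24 in the stationary phase (limma, Benjamini-Hochberg adjusted p under 0.05 and log2 of at least 1), and all 24 were among the 41. Of the 41, 26 lay in the 7 regions, 13 were probes with dim input, 1 was another gene-series probe and 1 lay elsewhere. The last, CGRfwd13614, lay in a raised forward run at numbers 13614 to 13615 (73.7% of the numbering). Its means were 0.39, 1.54, 0.83 and 0.29 on exponential 1, exponential 2, stationary 1 and stationary 2. This run was too short for the run rule and had no mirrored reverse run, so it was not counted as a region. Of the 24, 11 lay in the 7 regions and 13 were probes with dim input. CGRfwd00873, at the top of region 1, had log2 ratios of 2.89 in the exponential phase (limma adjusted p = 0.0366) and 2.28 in the stationary phase (limma adjusted p = 0.0394), each with an SE of 0.43. Some of the 41, such as CGRfwd00872, had no value on exponential 1, so their exponential mean is exponential 2 alone. The counts moved with the processing. With non-uniform spots kept they were 21 and 18, and among probes with values on all 4 arrays 23 and 18. With normexp background correction 967 and 936 probes passed, of which 6 and 2 were among the 41 and 24, and without exponential 1 the counts were 74 and 41. The normexp setting also left out dye normalization, so its counts do not isolate the background correction. Signals without dye normalization gave 63 and 42.

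The highest ratios on 3 of the 4 arrays came from a different kind of place, a block at 24.1% of the forward numbering. Its 10 raised tiling probes had a mean log2 ratio of 2.30 ± 0.15 (SD, n = 2) in the exponential phase and 2.78 ± 0.18 (SD, n = 2) in the stationary phase. CGRfwd04442 in this block reached 3.46 and 3.65, each with an SE of 0.12 (limma adjusted p = 5.7e-05 and 2.8e-05). The input signal of these probes was 0.77 to 9.21% of the array median. The 4 probes lying between those of the forward strand in number had 45.9 to 109% of it. Their median log2 ratios were 0.09 to 0.25 with non-uniform spots kept. Leaving out probes with dim input lowered the counts to 28 and 11.

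**Figure D2:**
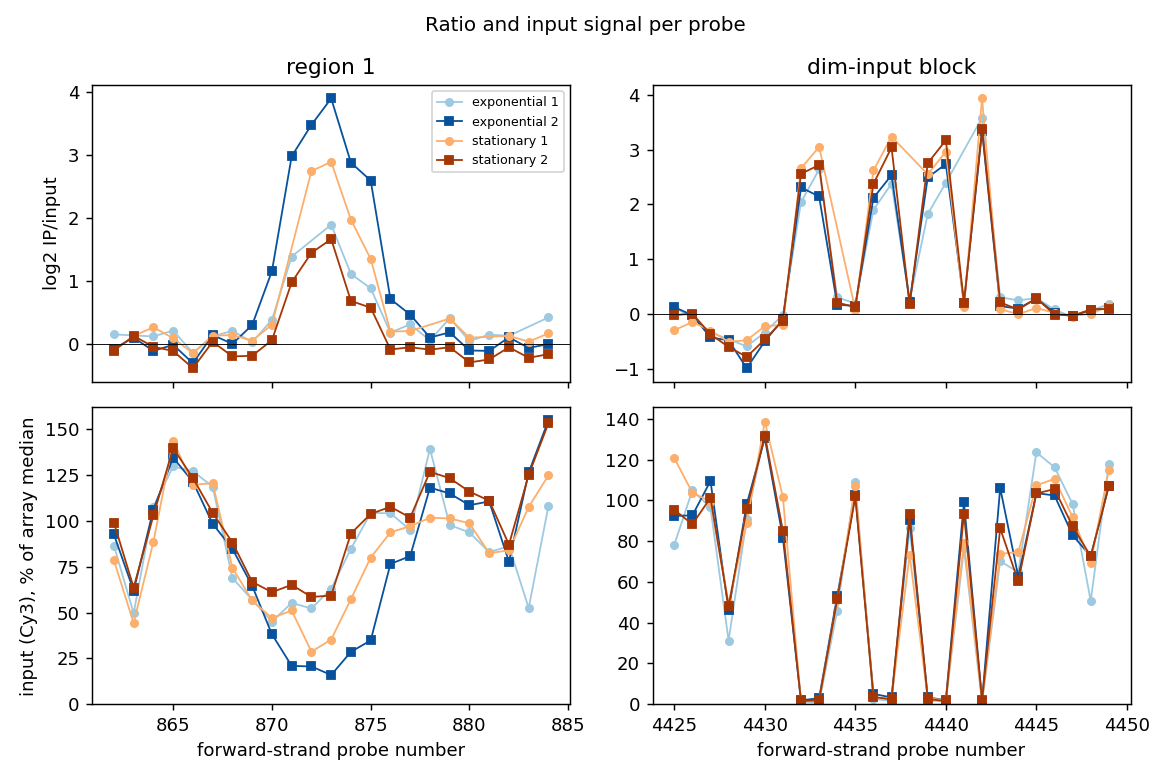
Log2 ratio of IP over input (upper row) and input signal in percent of the array median (lower row) of each forward-strand probe at region 1 (left) and in the dim-input block (right), by probe number, with 1 line per array and non-uniform spots missing from the upper row. Region 1 forms 1 smooth peak, while in the block raised probes with input under 10% alternate with probes near a log2 ratio of 0.

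The second question was whether binding differed between the growth phases. At 6 of the 7 regions the phases differed by less than the SD between the arrays of either phase. At region 3 they differed by more than both SDs. Region 3 rested on 5, 6, 5 and 5 of its 6 probes on exponential 1, exponential 2, stationary 1 and stationary 2, with different probes missing. With non-uniform spots kept its values were 1.13, 2.50, 1.41 and 0.57, and the phases then differed by less than the exponential SD. The stationary minus exponential log2 difference lay between -0.96 at region 3 and -0.23 at region 2, with an SE of 0.85. None of the 8 places tested, the 7 regions and the block, passed (0 calls; limma adjusted p between 0.776 and 0.794), and 0 had an unadjusted p under 0.05. With the experiment as a block the count was also 0 (limma adjusted p = 0.851 for each, SE 1.16). The SE is common to all 8 places and exceeds the SDs of the block (0.15 and 0.18). The block was higher in the stationary phase in both experiments, by 0.71 and 0.25. At the regions the within-experiment values had opposite signs. In experiment 1 all 7 regions were higher in the stationary phase, by 0.10 to 1.03 with a median of 0.82, and in experiment 2 all 7 were lower, by -2.10 to -1.34 with a median of -1.76. Without exponential 2 the median difference turned from -0.53 to 0.34. Region 4 rested on 1 of its 6 probes on exponential 1.

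**Figure D3:**
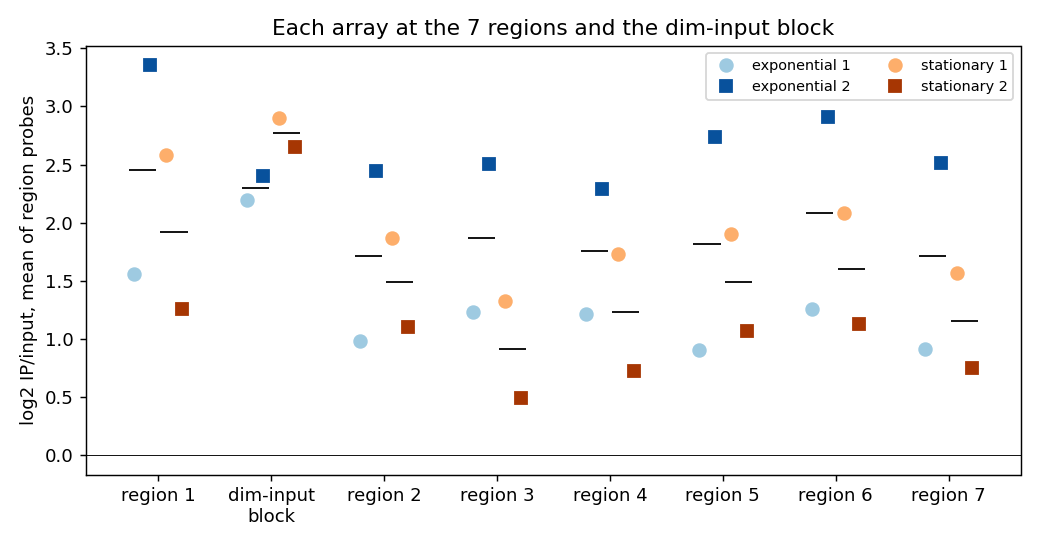
Log2 ratio of IP over input (y axis) at each region and at the dim-input block (x axis), with 1 point per array and a horizontal line at the mean of each phase (n = 2). In all 7 regions exponential 2 is the highest array, and stationary 1 lies above exponential 1.

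Across all probes, 0 of 38098 differed between the phases at an adjusted p under 0.05 (limma), and 1482 had an unadjusted p under 0.05, 216 of them higher and 1266 lower in the stationary phase. With the experiment as a block, 1541 of 31315 probes were called, 145 higher and 1396 lower in the stationary phase. These differences were small, with a median of 0.26 for the higher and -0.30 for the lower probes, and 0 reached log2 1 in size. Of the 1541, 9 lay in the 7 regions and 10 were among the 13 probes with dim input, all 10 higher in the stationary phase. The blocked probe fit borrows its spread largely from all probes. CGRrev17582 in region 1 was called with an SE of 0.20. Its exponential and stationary values were 0.66 and 0.57 in experiment 1 and 2.22 and 0.54 in experiment 2. The blocked fit of the regions had an SE of 1.16. A call among the 9 therefore does not show a like difference in both experiments. Without stationary 2 the fit without a block called 1217 probes, without exponential 1 it called 80, without exponential 2 it called 15, and without stationary 1 it called 0.

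Probes called at a log2 ratio of -1 or lower numbered 2 in the exponential phase and 7 in the stationary phase. CGRfwd04351 had log2 ratios of -1.004 in the exponential phase and -1.33 in the stationary phase (SE 0.13, limma adjusted p = 0.0338 and 0.0116), and CGRrev10704 had -1.01 and -0.91 (SE 0.14, limma adjusted p = 0.0338 and 0.0237). Runs of 1.5-fold lower ratios numbered 2 on the forward strand and 0 on the reverse strand, so no run could be mirrored. Some of the lowest single probes did lie at mirrored numbers, such as CGRfwd07751 (-0.57 and -0.94) and CGRrev10704. The run count therefore does not place low ratios on a single strand.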

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

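The phase difference at the 7 regions was opposite in the 2 experiments, and the tests below were chosen after this was seen. The median stationary minus exponential difference was 0.82 in experiment 1 and -1.76 in experiment 2, with all 7 regions on 1 side in each. With 1 array per phase and experiment, the difference between the experiments was not tested. The signs stayed opposite in all 7 regions with non-uniform spots kept.

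An exchange of the labels of the 2 arrays of experiment 2 is a candidate explanation. An exchange in experiment 1 would align the signs as well, and the measures below cannot tell these cases apart. Over probes outside the regions, the phase differences of the 2 experiments correlated with r = 0.48 (95% block bootstrap interval 0.45 to 0.50 over 28071 probes). As first written, the bound for this test took any positive correlation as evidence against an exchange, and it was met. The bound was changed afterwards, because with 1 pair of arrays per experiment a bias of single arrays gives either sign, and a second measure was added, the fall of the input signal from the ends of the numbering to its middle. The phases differed in it by 0.0028 (interval -0.017 to 0.023) in experiment 1 and 0.0046 (interval -0.0072 to 0.017) in experiment 2, so it separated nothing and an exchange stays open. A common enrichment factor per array stays open for the opposite signs at the 7 regions. For the place of region 3 among them the values do not decide. Region 4 had no reverse-strand value on exponential 1, and 6 regions were used for this test. After removing a common factor, these 6 departed from it with an SD 3.06 times that between strands. That ratio exceeds the bound first written (1.5), but strands of 1 array share its DNA, so the bound compared arrays with technical noise. Region 3 departed from the mean of the 7 regions by -0.95 and -0.89 in log2 excess over input (-0.92, SE 0.13, limma adjusted p = 0.0016 with the experiment as a block, lower in the stationary phase in both experiments), and by -0.67 with non-uniform spots kept and -0.94 without dye normalization. A factor that goes up in 1 experiment and down in the other does not move a region the same way in both. In log2 ratio the departures of region 3 were -0.62 and -0.27 and did not pass (limma adjusted p = 0.262). Region 3 was picked after its departure was seen, and the scale was not fixed beforehand. Its departure therefore does not decide against a common factor. A difference between the cultures of the 2 experiments was not tested.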

How the results depend on the processing

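Alternatives named as added in the processing part, the runs and the median region difference were defined after the data were seen. The 0 calls among the regions held under all 17 alternatives run, a design of 2 arrays against 2 that says little about stability. The median difference over the 7 regions (-0.53) was negative under 15 of 17, though near 0 with normexp (-0.06) and without stationary 2 (-0.0066), and reversed under 2: 0.34 without exponential 2 and 0.35 with grouping by the source field. Leaving out 1 array gave -1.31 to 0.34.

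Enriched probes (41 exponential, 24 stationary) became 967 and 936 with normexp, which also left out dye normalization. They became 62 and 38 with arrays scaled to 1 spread, 63 and 42 without dye normalization, and 21 and 15 at 4-fold. The counts were 21 and 18 with non-uniform spots kept and 23 and 18 with values on all 4 arrays. The stationary count was 11 without dim input and 58 with the source field. Leaving out 1 array gave 25 to 74 exponential and 25 to 45 stationary probes. The cause was not tested, except that dim-input, all-array and 4-fold settings admit fewer probes by construction.

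Probes differing between the phases (0, limma; 1482 at an unadjusted p under 0.05) became 1541 with the replicate block and 67 with a crossed replicate block, and 0 to 1217 with 1 array left out, where the lone array is assumed to vary like the others. The block moved no other count by over 1.5 times. Runs in the mean of all arrays (16) became 272 with normexp and 8 with at least 5 numbers in a row. The filter on probes not well above background moved nothing, since 11 spots on 1 array and 0 on the others failed it. Slide as a block was not run because it equals the experiment. Base-pair regions, upstream windows, gene lists and the motif were not run because positions were not used here.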

Other observations

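The tests here were chosen after the patterns were seen. Relative to the mean of the 7 regions on the same array, region 3 was lower in the stationary phase in both experiments, by -0.62 and -0.27 in log2 ratio, and region 2 higher, by 0.17 and 0.41. On this scale no region passed (limma with the experiment as a block, lowest adjusted p = 0.262, region 3). On a log2 scale of the excess over input, region 3 passed (difference -0.92, limma adjusted p = 0.0016). Regions 2 and 5 passed too (0.50 and 0.40, adjusted p = 0.0241 and 0.0445), but centring on a mean that holds region 3 raises the others. With region 3 left out, 0 of the other 6 regions passed (0.35 for region 2 and 0.25 for region 5, lowest adjusted p = 0.263). The call of region 3 depends on the scale, which was not fixed beforehand.

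Input signal fell from the ends of the probe numbering to its middle on all 4 arrays, by -0.13, -0.08, -0.13 and -0.08 log2 on exponential 1, exponential 2, stationary 1 and stationary 2.

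The block of dim probes had the highest ratios on 3 of the 4 arrays. SigC binding predicts that probes between the raised ones are raised too, since fragments of 600 to 1000 bp span neighbours. The highest of the 4 arrays' median log2 ratios for those probes, all of the forward strand, was 0.25, which argues against binding there. On the reverse strand the raised probes had consecutive numbers, so the test does not cover them. The raised probes had at most 9.21% of the median input on any array. The probes between them had 45.9 to 109% of it, which argues against 1 missing stretch spanning the forward-strand probes. A candidate explanation is that the DNA of single probes was missing or unmatched in this strain, so that 2 weak signals form the ratio. Probe sequences were not used here, and no biological explanation was tested.

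At the 7 regions the input signal lay below that of flanking probes on all 4 arrays, at 17.9 to 76.9% of it. Within an experiment, the array with the higher ratio at a region had the lower input signal there, relative to flanking probes. The median difference was -0.48 log2 in experiment 1 (6 of 7 regions) and -1.25 in experiment 2 (7 of 7), while IP signals differed by 0.24 and 0.36. Input is the same kind of DNA on every array and was not expected to follow IP. Both medians come from signals without dye normalization, where a difference made by that step would be absent (within 0.2), which argues against it as the source. The input was lower by more than this limit plus the SD of flanking probes in 5 of 7 regions in experiment 1 and 7 of 7 in experiment 2. The bound first written, 0.5 log2 in at least 6 regions, was met in experiment 2 but not in experiment 1 (3 of 7), where regions 3 and 4 showed no such difference (-0.13 and 0.12). Competition of the 2 labelled DNAs for the same probes may contribute, and it is a hypothesis: choosing the array with the higher ratio favours a lower input in part by construction, and a true difference in input DNA was not tested. If it holds, ratios at strong regions are not proportional to binding.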
